A study of Mus musculus with 4 samples.

How the data were processed

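The series holds 4 libraries of C2C12 mouse myoblasts (strain C3H), 2 transduced with an empty retroviral vector and 2 transduced to overexpress C/EBPβ. Per the labels' protocols, cells were grown in 10% fetal bovine serum, selected with G418 at 1200 µg/ml for 7 days as pools, left to proliferate for 2 days and differentiated from 90% confluency in 2% horse serum for 2 days. RNA went into stranded mRNA libraries sequenced on an Illumina instrument, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels do not say that equal replicate numbers mark a shared culture, batch or day, so the libraries were not treated as pairs.

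The authors deposited raw fragment counts per gene for each library. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.4 to GRCm38 and counted with featureCounts 1.4.6, whereas the file headers name featureCounts 1.5.1. Per the file headers, paired fragments were counted on the reverse strand against GENCODE M12, and the command line holds no option for fragments that map to several places or overlap several genes. Such fragments are left out by that program unless it is told otherwise, which lowers the counts of genes with near-identical copies. In the controls mt-Co2 was counted at 6.72 CPM against 3892 CPM for mt-Co1, which shares 51.1% of its 50-base windows with another annotated gene, for a cause that was not tested. A further table deposited by the authors holds, per the file headers, a mean normalised signal for each gene, a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value. DESeq2 is among the tools in the submitters' processing notes, with no version. The authors' mean signal is not the mean of these 4 libraries, since its ratio to that mean differs between genes, so other libraries may have entered that table. Of its 18378 rows, 5 carry no gene identifier and were not matched.

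The count files list 49585 genes, of which 26401 had a fragment in any library and 15886 passed edgeR's filterByExpr at its defaults (minimum count 10, minimum total 15). Symbols came from a GENCODE reference table that matched 49326 identifiers. Library sizes were scaled by TMM and the groups compared with edgeR 4.0.16 (R 4.3.3), glmQLFit with robust estimation and glmQLFTest, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library sizes, and the standard error of a log2 fold change was taken from the quasi-likelihood F statistic. An exact permutation of 2 against 2 libraries cannot give a 2-sided p below 0.333, so no single value was tested that way. The common biological coefficient of variation was 9.42%. Replicates were checked for duplication: the chi-square per degree of freedom was 20.0 between the control libraries and 28.5 between the overexpressing libraries, so none was a copy of another. Pearson's r of log2 CPM across genes was 0.995 and 0.993 within the groups and 0.939 to 0.958 between them.

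Before the data were examined, 29 gene lists, 9 of them context lists of other cell types or library composition, were fixed and tested with camera in limma 3.58.1 (competitive, 2-sided, preset inter-gene correlation of 0.01, adjusted over the lists). Members with too few fragments were not tested, and since a rise helps a gene pass that filter, counts among tested members of lists with many silent genes lean towards rises. The members past the threshold were counted over all genes and again adjusted over the list alone. The genes to name were also fixed by rule: 22 genes always, the 10 largest rises and 10 largest falls among protein-coding genes with a mean of at least 1 CPM and both overexpressing libraries on the same side of both controls, the 3 members with the smallest p in each list, and the 2 most abundant members of each context list. This rule gave 113 genes. Every other gene named was chosen after its values were seen, to complete small counts and to describe the added lists (91 genes were taken up this way); among them are Eya1, Myh4, Musk, Ak1, Cdk1, Cd36, Lif, Cxcl5, Lum, Lama2, Pdgfra, Fst, Lef1 and Xaf1. The values of a few genes are not reported here, although the counts of genes include them. A gene with no fragment in the controls was given as a lower bound against 3 fragments over the group, and one with 1 to 3 as a ratio with a 95% exact binomial interval. Sharing of sequence was measured as the percent of 50-base windows of a gene's transcripts found in transcripts of other genes in GENCODE M21. By that measure Lyz2, Kng1, Itgam, Jakmip1, H2-D1, C1s1, Myh4, Spp1, Hist1h2bc, Rpl3, Rpl10a and mt-Co1 share over 10% of their windows, and their counts are uncertain to that extent.

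The test was tested on simulated counts drawn from the real means and library sizes with 200 genes changed. Of 15572 genes tested there, it recovered 57.5% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 96.7% of those changed 4-fold, and 4 of 159 calls were false. In simulated lists camera with the preset correlation called the raised list and none of the others. With an estimated correlation the raised list passed only narrowly (camera adjusted p = 0.0461). The simulated genes varied independently of each other, so this check does not cover lists whose members vary together. Totals of 36461091 to 51537847 fragments set the precision, and intervals and floors cover counting error only.

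Alternatives covered other size factors (median-ratio, upper-quartile, library size alone), DESeq2 1.42.0, limma-voom, no low-count filter or a filter at 1 CPM in 2 libraries, other moderation settings, each library left out in turn, the replicate number as a block, an adjusted p threshold of 0.01, a test against a minimum fold of 1.5 (glmTreat), an estimated inter-gene correlation and fry. After the data were seen, 4 further lists (class I antigen processing, complement, glucocorticoid-responsive, myeloid granule) were written and tested in the same way; rises of some of their members prompted them, so their p-values are not given.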

Results

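Gene expression was measured by stranded mRNA sequencing in C2C12 cells, a mouse myoblast line that forms multinucleated myotubes when serum is lowered. The cells had been transduced with a retrovirus that was either empty or carried C/EBPβ, a leucine zipper transcription factor known from fat cell differentiation and acute-phase gene regulation. Drug-resistant pools were allowed to proliferate for 2 days and were then differentiated for 2 days, so that the comparison asks how differentiating myoblasts with extra C/EBPβ differ from those with the empty vector. Each group held 2 libraries. The empty-vector libraries held 45448661 and 51537847 fragments assigned to genes, and the overexpressing libraries 50493417 and 36461091. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

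Cebpb, the overexpressed gene, rose from 42.0 ± 1.04 to 472 ± 42.6 CPM (fragments of the gene relative to the scaled library total; mean ± SD, n = 2 in each group), an 11.2-fold difference. Its log2 fold change was 3.49 with a standard error (SE) of 0.11, and its adjusted p was 1.38e-06 in edgeR's quasi-likelihood test. Both overexpressing libraries, with 26235 and 16162 fragments, stood above both controls, with 1905 and 2087 fragments. The gene (ENSMUSG00000056501) lies on chromosome 2 from 167688915 to 167690418 on the plus strand of GRCm38, and the fold covers the fragments that aligned to this mouse gene, since the species of the vector's cDNA is not given in the sources used here. Of 15886 genes tested, 6873 changed, 3558 of them higher and 3315 lower in the overexpressing cells. At least 2-fold changes were found for 2645 genes, 1453 higher and 1192 lower. Without empty-vector replicate 2 the count was 4013 genes, 2158 higher and 1855 lower, and 770 genes were at least 2-fold lower.

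**Figure D1:**
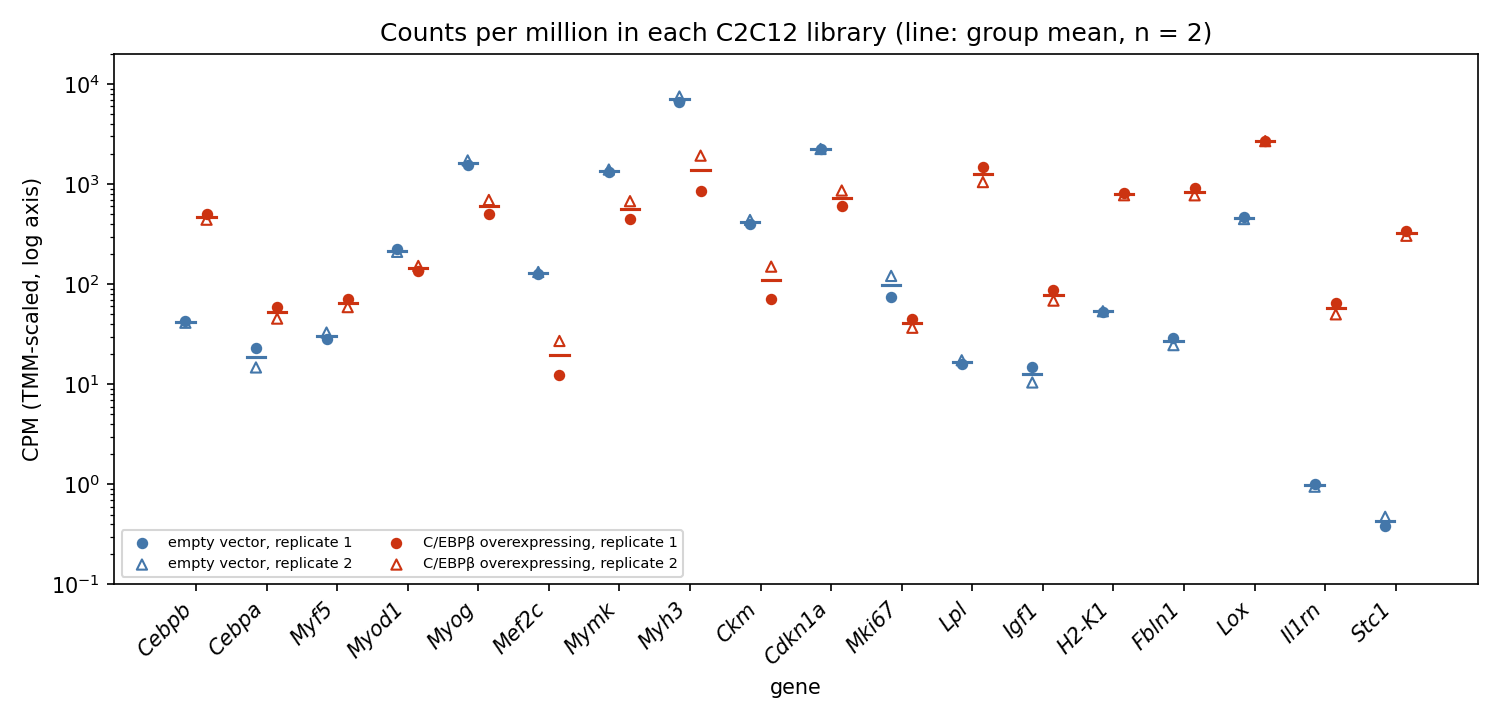
CPM of 18 genes (x axis) in each library on a log axis; filled circles are replicate 1, open triangles replicate 2, lines the group means, blue the empty vector and red C/EBPβ overexpression. Cebpb stands at 42.0 against 472 CPM, Myog at 1647 against 602 CPM and Lpl at 16.7 against 1271 CPM.

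Most regulators of muscle differentiation fell. Myog, which drives terminal differentiation of myoblasts, fell from 1647 ± 114 to 602 ± 132 CPM (n = 2 each), a log2 fold change of -1.45 (SE 0.17, adjusted p = 0.000514). Mef2c, a partner of the myogenic factors, fell from 130 ± 4.05 to 19.8 ± 10.4 CPM, and Myod1 fell less, from 217 ± 8.79 to 145 ± 11.1 CPM. Myf5, an early determination factor, moved the other way and rose from 30.5 ± 3.43 to 65.1 ± 8.51 CPM (adjusted p = 0.000439). Of the 13 myogenic transcription factors tested, 8 fell and 3 rose, and the counts were again 8 and 3 when adjusted over the list alone. Eya1 rose too, with a log2 fold change of 0.89, while Myf6 (0.46, adjusted p = 0.272) and Eya4 (-0.18, adjusted p = 0.152) did not pass. The list as a whole was lower than other genes, with a median log2 fold change of -0.59 and a camera adjusted p of 0.0172, against adjusted p = 0.483 with an estimated correlation. Mef2c lost its call without either control library (adjusted p = 0.0935 without replicate 1 and 0.134 without replicate 2).

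Genes of the contractile apparatus fell almost throughout. Myh3, the embryonic myosin heavy chain, fell from 7072 ± 634 to 1393 ± 757 CPM (n = 2 each), and Myl2, the slow and cardiac regulatory light chain, fell from 6.68 ± 0.46 to 0.116 ± 0.029 CPM, 57.9-fold. Of 45 sarcomere genes tested, 44 fell and none rose, both over all genes and adjusted over the list alone, and the median log2 fold change was -1.60. Myh4, a fast myosin heavy chain, did not pass (log2 fold change -0.52, SE 0.50). The sarcomere list took 5.03 ± 0.44% of assigned fragments in the controls and 1.88 ± 0.57% in the overexpressing cells. Among genes of excitation-contraction coupling and the neuromuscular receptor, 22 of 23 fell, as they did adjusted over the list alone, with a median of -1.03. They included Cacng1, a subunit of the muscle calcium channel (log2 fold change -1.03, SE 0.11), and Chrnb1, a subunit of the acetylcholine receptor (-0.96, SE 0.13), and the remaining one was Musk (-0.01, SE 0.10). Of 15 muscle energy metabolism genes 14 fell, again the same number adjusted over the list alone, with a median of -1.65. Ckm, the muscle creatine kinase, fell from 421 ± 25.5 to 110 ± 56.1 CPM and Pfkm, muscle phosphofructokinase, from 444 ± 5.47 to 169 ± 33.8 CPM, while Ak1 stood at -0.09 (SE 0.10). The camera adjusted p was 1.0e-21 for the sarcomere, 7.0e-10 for excitation-contraction coupling and 1.2e-07 for energy metabolism, and for all 3 lists adjusted p = 0.483 with an estimated correlation. All 45 sarcomere genes were higher in overexpressing replicate 2 than in replicate 1, with a median log2 difference of 0.82. Myh3 lost its call without control replicate 1 (adjusted p = 0.0527), without control replicate 2 (0.0894) and without the low-count filter (0.0700), Ckm likewise (0.139, 0.208 and 0.0845), and Myh4 passed without overexpressing replicate 2 (5.65e-28).

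Most genes tested for myoblast fusion and adhesion fell, while a few rose. Mymk and Mymx, the membrane proteins that drive myoblast fusion, fell 2.43-fold and 2.58-fold, Mymk from 1368 ± 45.8 to 563 ± 161 CPM (n = 2 each, adjusted p = 0.00242). Cdh15, the muscle cadherin, fell from 777 ± 0.312 to 358 ± 38.2 CPM. Of 17 genes for myoblast fusion and adhesion 10 fell and 4 rose, or 11 and 4 adjusted over the list alone, with a median of -0.53 (camera adjusted p = 0.00716, against adjusted p = 0.483 with an estimated correlation). The risers were Ehd2, Dock1, Elmo1 and Il4ra, with log2 fold changes of 0.70, 0.54, 0.83 and 0.34. Il4ra lost its call without control replicate 2 (adjusted p = 0.155) and without overexpressing replicate 2 (0.104).

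Genes of satellite and reserve cells, the undifferentiated cells of muscle and of myoblast cultures, moved both ways. Hes1 and Heyl, targets of Notch signalling, fell 2.88-fold and 2.00-fold, with a log2 fold change of -1.53 (SE 0.13, n = 2 each) for Hes1. The Notch ligand Jag1 rose 3.96-fold, from 11.7 ± 1.08 to 46.4 ± 4.25 CPM, and Sdc3, Vcam1 and Notch2 rose as well. Of 19 genes 11 fell and 4 rose, also when adjusted over the list alone, with a median of -0.54 and a camera adjusted p of 0.0472, against adjusted p = 0.483 with an estimated correlation. Pax7, the satellite cell transcription factor, stood at a mean of 34.8 CPM in the controls and 46.2 CPM in the overexpressing cells and did not pass (log2 fold change 0.41, SE 0.22, adjusted p = 0.203). The call for the list ended without control replicate 1 (adjusted p = 0.149), without overexpressing replicate 1 or 2 (0.0527 and 0.0889) and with a filter at 1 CPM (0.0641), and Pax7 passed without the same 3 libraries (0.00528, 0.0332 and 0.000289).

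Proliferation genes fell together with those of muscle. Mki67, a marker of cycling cells, fell from 97.9 ± 32.9 to 40.8 ± 5.61 CPM (n = 2 each, adjusted p = 0.0188), and Rrm2, a subunit of ribonucleotide reductase, fell from 217 ± 17.8 to 100 ± 6.74 CPM. Of 39 cell cycle genes 37 fell and none rose, or 38 and none adjusted over the list alone, with a median of -1.05 and a camera adjusted p of 2.8e-13 (adjusted p = 0.483 with an estimated correlation). Cdk1 (log2 fold change -0.50, adjusted p = 0.0545) and E2f1 (-0.12, adjusted p = 0.279) did not pass over all genes. Cdkn1a, the cyclin-dependent kinase inhibitor p21 that rises when myoblasts leave the cell cycle, also fell, from 2245 ± 4.95 to 735 ± 184 CPM (adjusted p = 0.000478), while Cdkn1c, another inhibitor (log2 fold change -0.46, adjusted p = 0.0982), and Ccnd1, cyclin D1 (0.23, adjusted p = 0.0710), did not pass. Without overexpressing replicate 1, Cdkn1c passed as lower (adjusted p = 7.73e-05) and Ccnd1 as higher (0.0319), as Ccnd1 did with library sizes alone (0.0294). Mki67 lost its call without the low-count filter (0.0578), and Cdk1 passed without control replicate 1 (0.0135) and without overexpressing replicate 1 or 2 (9.77e-07 and 0.00577), and also with all libraries in DESeq2 (0.0125), limma-voom (0.0386), edgeR with median-ratio size factors (0.0486) and edgeR without robust estimation (0.0344).

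Genes of the fat cell programme rose in part. Lpl, lipoprotein lipase, rose 76.2-fold, from 16.7 ± 1.04 to 1271 ± 313 CPM (n = 2 each; log2 fold change 6.25, SE 0.21, adjusted p = 4.69e-06). Pparg, the nuclear receptor of fat cell differentiation, rose by a log2 fold change of 0.78 (SE 0.15, adjusted p = 0.00534). Fabp4, a fatty acid binding protein, had 3 fragments in the controls and 189 in the overexpressing cells, a ratio of 67.5 with a 95% counting interval from 22.7 to 330.2, and Plin1, a lipid droplet protein with no fragment in the controls, was at least 23.9-fold higher against a floor of 3 fragments over the group. Of 25 adipogenic genes listed 15 had enough fragments to be tested, and of these 11 rose and 2 fell, also when adjusted over the list alone, with a median of 0.85 and a camera adjusted p of 0.000180 (adjusted p = 0.483 with an estimated correlation). Cd36, a fatty acid transporter, and Gpd1 fell, with log2 fold changes of -1.94 and -1.43, while Fasn (-0.23) and Scd1 (-0.10), enzymes of fatty acid synthesis, did not pass. Of the other C/EBP family members, Cebpa rose from 18.8 ± 5.74 to 52.4 ± 9.83 CPM and Ddit3 from 26.9 ± 0.616 to 36.7 ± 4.40 CPM, whereas Cebpd stayed at 8.78 ± 0.754 and 8.89 ± 1.35 CPM. These 2 of 4 tested were also those that passed adjusted over the list alone (camera adjusted p = 0.355). Cd36 lost its call without either control library (adjusted p = 0.152 and 0.222) and without the low-count filter (0.0930), Ddit3 without control replicate 1 (0.0568), and Fasn passed without overexpressing replicate 2 (0.0157).

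Cytokine and acute-phase genes had the highest median fold change of the 29 lists fixed beforehand. Il1rn, the interleukin-1 receptor antagonist, rose from 0.979 ± 0.0428 to 57.4 ± 10.4 CPM (n = 2 each), and Ptx3, a pentraxin of the acute phase, from 0.872 ± 0.249 to 76.8 ± 14.1 CPM. C3, the central complement component, rose 74.9-fold (log2 fold change 6.23, SE 0.29, adjusted p = 7.92e-06), and the chemokine Cxcl5 rose 20.1-fold. Of 31 cytokine and acute-phase genes tested from 41 listed, 25 rose and 2 fell, or 26 and 4 adjusted over the list alone, with a median of 2.77 and a camera adjusted p of 2.8e-24 (adjusted p = 0.412 with an estimated correlation). The genes that fell were Lif and Tnfaip3, with log2 fold changes of -1.36 and -0.92. Il6 stood near the detection limit, at 0.0956 ± 0.0234 and 0.242 ± 0.0445 CPM, and did not pass (adjusted p = 0.0679), nor did Il11, Ccl5 and Ptgs2. Macrophage markers moved beside this group, since 3 of 6 tested from 12 listed rose and Itgam, which shares 66.3% of its 50-base windows with another annotated gene, fell, or 4 and 1 adjusted over the list alone, with a median of 0.83 and a camera adjusted p of 0.00191 (adjusted p = 0.483 with an estimated correlation). Lyz2, a lysozyme of myeloid cells with a close relative in Lyz1, rose from 0.107 ± 0.0393 to 27.3 ± 1.64 CPM, Cd14 rose from 5.07 ± 0.452 to 11.4 ± 0.682 CPM, and Csf1r had a log2 fold change of 1.19. Without control replicates 1 and 2 in turn, Lif had an adjusted p of 0.160 and 0.199 and Csf1r of 0.143 and 0.116, Csf1r also lost its call without overexpressing replicate 2 (0.151), and Itgam lost its call without control replicate 2 (0.0537) and overexpressing replicate 1 (0.154). In DESeq2 the adjusted p was 0.111 for Csf1r and 0.110 for Itgam, and without the low-count filter it was 0.0699 for Lif. Without overexpressing replicate 2, Il11 and Ptgs2 passed as lower (0.0184 and 3.74e-06), as Ptgs2 did in limma-voom (0.0443).

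Matrix genes rose broadly. Lox, which crosslinks collagen, rose 5.87-fold (n = 2 each; log2 fold change 2.55, SE 0.13, adjusted p = 1.05e-05), and Fbln1, a matrix glycoprotein, rose 31.2-fold, from 27.0 ± 3.30 to 843 ± 97.1 CPM. Of 41 collagen and matrix genes 32 rose and 2 fell, the same counts as adjusted over the list alone, with a median of 0.81 and a camera adjusted p of 7.7e-18 (adjusted p = 0.483 with an estimated correlation). The list took 2.88 ± 0.33% of assigned fragments in the controls and 6.31 ± 0.02% in the overexpressing cells. Lum, a small proteoglycan, and Lama2, the laminin chain of muscle basement membrane, fell, with log2 fold changes of -1.56 and -0.26. Of 19 genes of smooth muscle and the TGF-β response 12 rose and 2 fell, also adjusted over the list alone, with a median of 0.52 and a camera adjusted p of 3.7e-05 (adjusted p = 0.483 with an estimated correlation). Ccn2, a matricellular protein, rose from 82.1 ± 9.80 to 611 ± 33.4 CPM and Tagln, an actin-binding protein of smooth muscle, from 88.9 ± 7.25 to 228 ± 0.239 CPM, while Tgfb3 and Tgfbr2 fell (-0.62 and -0.54). Beside these groups, markers of fibro-adipogenic progenitors, the fibroblast-like cells of muscle, rose for 6 of 10 genes and fell for Lum, or 7 and 1 adjusted over the list alone, with a median of 0.96 and a camera adjusted p of 8.9e-05 (adjusted p = 0.483 with an estimated correlation). Pdgfra had a log2 fold change of 2.84 (SE 0.32). Of 8 bone and cartilage markers tested from 13 listed, Spp1, Alpl, Comp and Runx2 rose and Sox9, Dmp1 and Col10a1 fell, also adjusted over the list alone, and their median of -0.08 had the opposite sign to their mean of 0.86 and to the test (camera adjusted p = 0.448). Lama2 lost its call without control replicates 1 or 2 (adjusted p = 0.118 and 0.0885), without overexpressing replicate 1 (0.114) and with library sizes alone (0.0558), and Alpl without control replicate 2 (0.0517).

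Bmp4, a BMP ligand, rose from 75.7 ± 4.98 to 202 ± 3.24 CPM (n = 2 each), and the BMP antagonists Nog and Fst fell, with log2 fold changes of -1.87 (SE 0.17) and -1.10 (SE 0.11). Of 17 BMP response genes 9 rose and 2 fell, or 9 and 3 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 0.0716). Sfrp1, a secreted Wnt inhibitor, rose 275-fold, from 2.02 ± 0.102 to 559 ± 15.7 CPM (adjusted p = 4.98e-08), and the Wnt feedback gene Nkd2 rose 13.5-fold. The Wnt effectors moved both ways: Lef1 and Tcf7 fell, 2.15-fold and 2.01-fold, while Tcf7l2 rose (log2 fold change 0.46, SE 0.11). Of 22 Wnt response genes 12 rose and 6 fell, also adjusted over the list alone, with a median of 0.55 and a camera adjusted p of 3.7e-05 (adjusted p = 0.483 with an estimated correlation). Igf1 rose from 12.7 ± 3.18 to 77.8 ± 13.0 CPM and Igfbp4, an IGF binding protein, 30.8-fold, from 10.3 ± 1.15 to 316 ± 66.6 CPM. With Igfbp7 and Igfbp6 (log2 fold changes 1.32 and 0.47), 4 of the 16 IGF axis genes rose and 6 fell, also adjusted over the list alone. Those that fell included the binding proteins Igfbp5 and Igfbp2 (log2 fold changes -0.89 and -0.74) and H19, an imprinted noncoding RNA, which fell 2.75-fold. The median of the IGF list was -0.05, against a mean of 0.28 and a test in the upward direction (camera adjusted p = 0.408). The BMP list passed without overexpressing replicate 1 (adjusted p = 0.0412) and without replicate 2 (0.0350).

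Within the interferon response list, the largest rises were of genes of class I antigen presentation. H2-K1, a classical class I heavy chain on chromosome 17 (33996017 to 34000333, GRCm38), rose from 53.5 ± 0.291 to 794 ± 25.2 CPM (n = 2 each; log2 fold change 3.89, SE 0.10, adjusted p = 9.03e-07). Tap1, a peptide transporter, rose 16.8-fold, and Psmb8, a subunit of the immunoproteasome, had a log2 fold change of 7.76 (SE 0.30). Of 29 interferon response genes 10 rose and 6 fell, also adjusted over the list alone, with a median of 0.18 and a camera adjusted p of 0.000475 (adjusted p = 0.497 with an estimated correlation). Xaf1, an interferon-induced gene, fell (log2 fold change -0.94, SE 0.14). The call for the list ended without control replicate 1 (adjusted p = 0.0869) and without overexpressing replicate 1 (0.0764).

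Stc2, a secreted glycoprotein of the stress response, fell from 19.7 ± 1.77 to 4.09 ± 1.26 CPM (n = 2 each), and Chac1, a glutathione-degrading enzyme, fell 1.66-fold. Of 31 genes of the integrated stress and unfolded protein responses 12 fell and 4 rose, also adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.0515), and the risers were Ddit3, Xbp1, Calr and Vldlr. Of 23 cholesterol synthesis genes 7 fell and none rose, or 6 and none adjusted over the list alone, with a median of -0.33 and a camera adjusted p of 0.0165 (adjusted p = 0.665 with an estimated correlation). Dhcr7, the last enzyme of the pathway, fell from 123 ± 0.687 to 61.4 ± 10.2 CPM. Of 20 immediate early genes 8 fell and 3 rose, or 10 and 3 adjusted over the list alone (median -0.21, camera adjusted p = 0.179), Egr3 falling 2.58-fold and Fosl2, Fosl1 and Myc rising. Of 22 atrophy and autophagy genes 7 rose and 7 fell, or 8 and 8 adjusted over the list alone, and the median of 0.12 and mean of 0.19 had the opposite sign to the test (camera adjusted p = 0.782). In that list Trim63, a ubiquitin ligase of the sarcomere, fell from 70.4 ± 4.42 to 19.1 ± 4.90 CPM, Fbxo32, another atrophy ligase, stood at 86.4 ± 8.17 and 82.8 ± 3.87 CPM (adjusted p = 0.623), and Mstn, which encodes myostatin, rose from 0.363 ± 0.101 to 2.24 ± 0.319 CPM. The cholesterol list lost its call without overexpressing replicate 1 (adjusted p = 0.0655), Xbp1 without any library but overexpressing replicate 1 (up to 0.151), Calr without either control library (0.0685 and 0.0654), and Ddit3 and Fosl1 without control replicate 1 (0.0568 and 0.0573). The stress list passed without control replicate 1 (adjusted p = 0.0195), without overexpressing replicate 2 (0.000544) and with median-ratio size factors (0.0489).

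The remaining lists served as context for other cell types and for library composition. Tubb3, a neuronal tubulin, fell from 39.8 ± 2.77 to 16.3 ± 1.80 CPM (n = 2 each), as did Map2, Nefl and Nefm, so that 4 of 6 neural and glial genes tested from 10 listed fell and 1 rose, also adjusted over the list alone (median -1.66, camera adjusted p = 0.00220, adjusted p = 0.483 with an estimated correlation). Of 3 endothelial genes tested from 8 listed, Cldn5 and Tek fell, also adjusted over the list alone (camera adjusted p = 0.312), and Vwf stood at 1.25 ± 0.141 and 1.45 ± 0.379 CPM. None of 13 mitochondrially encoded genes passed in edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.462). Only 1 (mt-Nd1) had an unadjusted p under 0.05 in edgeR, and the same gene passed in DESeq2 and limma-voom. All genes annotated on the mitochondrial chromosome together took 1.77 ± 0.17% of fragments in the controls and 1.62 ± 0.14% in the overexpressing cells. Of 28 nuclear genes of oxidative phosphorylation 12 fell and none rose, or 13 and none adjusted over the list alone (median -0.26, camera adjusted p = 0.00652, adjusted p = 0.626 with an estimated correlation). Rpl3, Rpl10a and Rps14 rose among 30 ribosomal protein genes, or 1 adjusted over the list alone (camera adjusted p = 0.358), and Hist1h2bc fell among 5 replication-dependent histone genes tested from 17 listed, also adjusted over the list alone (camera adjusted p = 0.587). Tek lost its call without any library but overexpressing replicate 1 (adjusted p from 0.0710 to 0.173) and in DESeq2 (0.154), Rps14 without any but overexpressing replicate 2 (0.0578 to 0.173) and Rpl3 without either control library (0.141 and 0.116).

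Among single genes, the largest rises were of genes close to silent in the controls. Angptl7, a secreted angiopoietin-like protein (chromosome 4, 148495183 to 148500460), went from 0.0521 ± 0.0102 to 220 ± 13.8 CPM (n = 2 each, adjusted p = 4.12e-08), on 5 control fragments. Stc1, a secreted glycoprotein hormone, rose 748-fold, from 0.428 ± 0.0659 to 324 ± 26.4 CPM, and Lama1, a laminin chain, rose from 0.0692 ± 0.0979 to 96.9 ± 10.8 CPM. Another 7 genes had no control fragment and were higher by at least 323-fold (Kng1), 274-fold (Vit), 160-fold (Cybb), 131-fold (Slc36a2), 85.4-fold (Nrg2), 83.6-fold (Wfdc21) and 78.9-fold (Pla2g2d) against a floor of 3 fragments over the group, which covers counting error only. The largest falls after Myl2 were of Ms4a8a (log2 fold change -5.56, SE 0.71) and of Mybpc2, a fast myosin-binding protein (-5.37, SE 0.33), followed by Fxyd6, Jakmip1, Nptx1, Stum, Sult2b1 and Ptgds, which fell from 29.9-fold (Fxyd6) to 18.6-fold (Ptgds). Kng1 shared 17.2% of its 50-base windows with Kng2 or other genes, and Jakmip1 47.0%, so that their counts are uncertain. Nptx1 lost its call without control replicates 1 and 2 in turn (adjusted p = 0.0709 and 0.129). Cybb lost its call without either control library (adjusted p = 0.0854 and 0.123) and without the low-count filter (0.160).

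**Figure D2:**
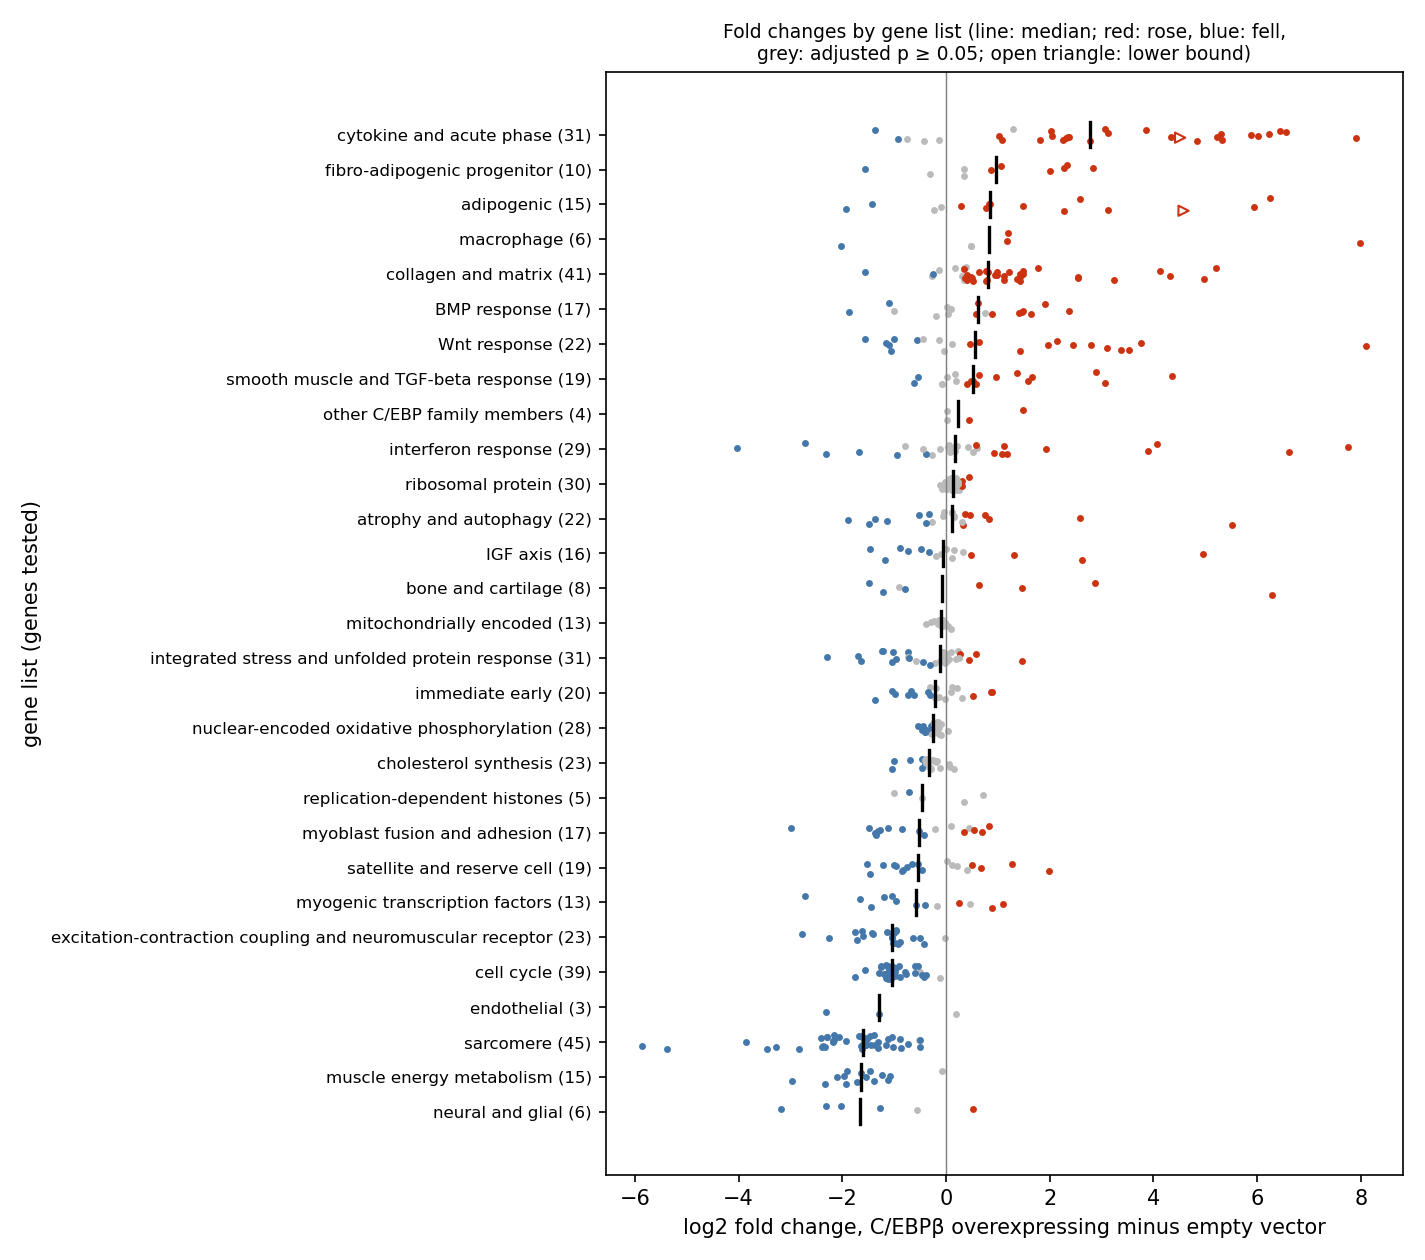
Log2 fold change (x axis, overexpressing minus empty vector) of each tested gene in the 29 gene lists (y axis, sorted by median); red points rose, blue points fell, grey points did not pass, black lines are medians and open triangles are lower bounds for genes with no control fragment. Sarcomere genes lie to the left (median -1.60) and cytokine and acute-phase genes to the right (median 2.77).

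The authors' deposited table of the same comparison was set beside these results. In the authors' deposited table, an adjusted p under 0.05 was given for 6798 genes, 2960 of them higher and 3838 lower. Of 15883 genes in both, 6737 were called in the authors' deposited table and 6871 here, 6018 were called in both, and all of these had the same direction. Fold changes had a Pearson r of 0.976 across genes, which are not independent replicates. For Cebpb the authors' deposited table gives a log2 fold change of 3.41, and for Myog -1.44. For Lama1 it gives 2.28 (SE 0.72), far smaller than the rise found here, and the cause of this difference was not tested. The table rests at least in part on the same libraries and is not independent evidence.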

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

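No alternative was added after the results were seen. Cebpb kept its direction and its call in all alternatives, with log2 fold changes from 3.40 to 3.56, and none of the 6873 main calls was called in the opposite direction under any scaling, tool, filter or left-out library. Leaving out 1 library gave from 4013 to 7541 changed genes, 2158 to 3795 higher and 1855 to 3746 lower, and 770 to 1412 at least 2-fold lower; the lone library of a group is then assumed to vary like the other group, so adjusted p without an overexpressing library rest on the spread of the controls, and the low end, without empty-vector replicate 2, comes with fewer samples. An adjusted p under 0.01 gave 4209 genes, 2261 higher and 1948 lower, as a stricter threshold must, and 3949 genes were then called both here and in the authors' deposited table. DESeq2 called 5819 genes and limma-voom 6886. With library sizes alone 58.1% of calls were higher, against 51.8%, and the largest shift of the median of all genes under another scaling was 0.0553 in log2. With the replicate number as a block 7599 genes were called; the libraries with equal numbers deviated together with a correlation of 0.147, but 2 pairs do not show that the numbers pair the samples. The block ended the call for the satellite and reserve cell list (adjusted p = 0.0837) and made those for the BMP list (0.0432) and the stress list (0.00709), as well as those for Pax7 (0.0320), Cdkn1c (0.0339) and Ccnd1 (0.0283). Of 29 lists 18 passed with the preset correlation, 0 with an estimated correlation and 10 with fry, which does not compare a list with other genes; the lowest adjusted p with an estimated correlation was 0.412, and with fry the sarcomere list had 0.0530. The cause of these differences was not tested. Over 2828 values of named genes under alternatives, 2711 kept their side of the threshold, 23 of them uncalled values whose sign differed, while 84 lost the call, 33 gained it and 0 called values reversed; 22 of the lost calls came without empty-vector replicate 1 and 27 without replicate 2. Depth limits genes with few control fragments, whose fitted folds are not precise.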

Other observations

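The tests of the 4 lists described here, of admixture and of a general interferon response were chosen only after the results were seen, and since rises of some members prompted the lists, their counts are descriptions and no p is given for them. Class I antigen processing genes rose as a group in the overexpressing cells: 17 of 22 rose and none fell, with a median log2 fold change of 1.95. H2-D1, a class I heavy chain, rose from 50.8 ± 0.582 to 460 ± 15.9 CPM (n = 2 each), B2m, the shared light chain, from 337 ± 22.7 to 1275 ± 43.9 CPM, and Nlrc5, a transcriptional activator of class I genes, from 2.31 ± 0.0719 to 31.2 ± 4.13 CPM. Of 21 complement genes listed 11 had enough fragments to be tested, a filter that a rise helps to pass; 10 of these rose and Cfp did not pass, with a median of 2.31, and C1s1, a protease of the classical pathway, rose 9.03-fold (log2 fold change 3.18, SE 0.26). Of these lists, 5 class I genes and 2 complement genes also stood in the lists fixed beforehand, as did 3 of the myeloid granule genes and 2 of the glucocorticoid-responsive genes described next.

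Of 21 genes of myeloid granules and bacterial defence listed 10 had enough fragments to be tested; 8 of these rose and Ncf1 and Itgam fell, with a median of 7.22, or 6.64 with genes at 0 in the controls set to their lower bound. Slpi, a secreted protease inhibitor, rose from 0.297 ± 0.0562 to 35.2 ± 1.61 CPM (n = 2 each), and Camp, an antimicrobial peptide, from 0.0858 ± 0.0374 to 3.79 ± 0.712 CPM. Of 14 glucocorticoid-responsive genes tested from 16 listed, 7 rose and 2 fell, with a median of 0.32. Klf15 (log2 fold change 5.52), Klf9 (20.1 ± 1.14 to 40.1 ± 2.60 CPM), Errfi1, Nfkbia, Mt1, Mt2 and Sgk1 rose, and Fkbp5 and Tsc22d3 fell (-0.73 and -0.56).

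The overexpressing libraries differed from each other in muscle genes and in some other lists. All 45 sarcomere genes were higher in replicate 2 than in replicate 1, with a median log2 difference of 0.82, against 0.14 between the control libraries (replicate 2 minus replicate 1), while the medians were 0.35 and 0.20 for cholesterol synthesis, with 23 of 23 genes higher in overexpressing replicate 2, and -0.19 and 0.34 for the cell cycle. After replicate 1 was thinned to the total of replicate 2 the median difference was 0.77. CPM are already scaled for depth and most of these genes had many fragments, so thinning could hardly change the median and the test decided little. Admixture of control RNA would need a share between quartiles of 15.3 and 26.1% to account for the sarcomere list; a first test on 39 genes nearly absent from replicate 1, at a median of 11.1% of the control level in replicate 2, decided nothing, and in the test that replaced it 25 genes, some of them sarcomere genes (Myl2) and others not (Sult2b1, Nptx1), had upper count limits in replicate 2 below the lower quartile of that share. These 25 genes argue against admixture at the share that the sarcomere list needs. A further 151 genes stood over 16-fold above the controls in replicate 1. They were lower in replicate 2 by a median of 22.7% (quartiles 7.32 and 36.5%), which lies between the quartiles of the share needed. These 151 genes were picked by their level in replicate 1, which by itself favours a lower level in replicate 2. Their fall therefore cannot decide for or against admixture. Admixture as the whole cause is thus argued against by the 25 genes, among them Nptx1, at 6.03% of its control level of 161 CPM in replicate 2. A smaller share that adds to another cause stays open. Cebpb stood at 502 CPM in replicate 1 and 442 CPM in replicate 2, and no biological explanation was tested.

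The rise of class I genes may reflect something other than a general interferon response. Of the other 24 interferon response genes 5 rose and 6 fell, 2 of the latter, Ifit2 and Xaf1, at 1 CPM or more in the controls, and the highest log2 fold change among the 24 was 1.17, against a lowest of 1.92 among H2-K1, B2m, Tap1, Psmb8 and Psmb9; Ifit2 lost its call without control replicates 1 and 2 in turn (adjusted p = 0.0541 and 0.127). Reads shared with near-identical genes are argued against for B2m, Tap1, Psmb8 and Psmb9, which shared at most 0.442% of their windows with other genes, while H2-K1 (9.63%) and H2-D1 (12.8%) shared more and their counts are uncertain to that extent. A regional change on chromosome 17 as the whole cause is argued against by the rises of B2m and Nlrc5 on other chromosomes, but a regional part stays open: the 25 other tested genes within 300 kb of Psmb8, Psmb9 and Tap1 had a median of 0.40 (0.26 for the 22 outside the class I list), 11 of the 25 rose and 1 fell, and the rises included H2-K1, H2-K2 (log2 fold change 3.40), H2-DMa (1.30), H2-DMb1 (0.0112 to 0.954 CPM) and H2-DMb2 (0 to 0.578 CPM). No biological explanation was tested.

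Leukocytes in the overexpressing cultures could in principle bring Lyz2, Cd14 and the granule genes. The summed counts of Ptprc, Adgre1, Tyrobp, C1qa, C1qb and Aif1 were 3 fragments in the controls and 5 in the overexpressing libraries, a ratio of 1.79 with a 95% counting interval from 0.347 to 11.5, while Lyz2 rose 253-fold to 27.3 CPM. Tyrobp, C1qa and C1qb, abundant in macrophages, had 0 fragments in all 4 libraries. The 6 summed genes were the members of the macrophage list with too few fragments to be tested, and Lyz2 and Cd14, which rose, were not among them. A panel this low gives a ratio interval too wide to decide. The absence of Tyrobp, C1qa and C1qb beside 27.3 CPM of Lyz2 argues against macrophages as the source. Other leukocytes stay open, and no biological explanation was tested.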
